A study of Homo sapiens with 34 samples.

How the data were processed

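RNA was measured in 34 archival colorectal cancer tissue samples. Per the labels' protocols, total RNA was fragmented, made into cDNA, ligated to duplex adaptors carrying molecular identifiers, enriched with an exome capture that includes untranslated regions, and sequenced on a NovaSeq instrument. Capture favours targeted exons, so levels of different genes also reflect capture efficiency, and the same gene across samples is the safer comparison.

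The authors deposited 1 isoform table per sample. Per the file headers each table gives, for 87725 transcripts under 29972 gene names, an expected count, TPM, FPKM and the isoform share in percent, in the layout of RSEM. The expected count, per the file headers, is an estimate that need not be whole, in which reads shared by transcripts are divided. The deposited TPM is the authors' measure of transcripts, scaled within each sample. The deposited FPKM values were not used. The deposited percent gives each isoform's share within its gene. The genome build is GRCh38, per the submitters' processing notes. The aligner, the tool version, the annotation release, the use of strand and whether reads were collapsed by molecular identifier are not given in the sources used here, so counts may include amplification copies.

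Expected counts were summed per gene name. XIST, TSIX and Y-linked genes, 105 names in all, were left out, which kept 29867 names. Genes with at least 1 CPM in at least 10 samples were kept (15636 genes). Levels are CPM after edgeR's TMM scaling (factors 0.85 to 1.45), with log2 values computed with a prior count of 2. CPM is not divided by transcript length. The gene lists and marker lists were fixed before the data were examined, and 371 of their 380 entries were found, 5 of them under an older symbol. None of the mitochondrially encoded genes was found, and of the lung alveolar and adipocyte markers too few passed the filter to be tested. Gene positions and exon overlaps come from the GENCODE annotation of GRCh38.

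Total expected counts ranged from 6936407 to 26096588. With no labelled treatment, outcome or batch, all samples formed 1 group. For each list the median level, the median SD of log2 CPM and the mean pairwise correlation were set against 10000 random lists, matched on expression in 20 bins for the last 2 measures. A score was the mean z-scored log2 CPM of a list. Correlations used Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples (10000 for relations without 2 samples and for library measures), Benjamini-Hochberg adjusted within each family. These p-values measure the spread between these samples. Fits of all genes against log2 CPM of TK1 or TYMP used edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, robust) on expected counts rounded to whole numbers, with adjusted p from the Benjamini-Hochberg method at 0.05. Slopes are log2 change per doubling of the covariate gene, and the SE was derived from the F statistic. Because the covariate is itself a measured level in the same libraries, it carries the same scaling error as the genes. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and with an estimated one.

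On simulated counts with planted slopes, the TK1 fit recovered 69% of genes with a slope of 0.5 and 100% with a slope of 1, among 15636 genes, with 3.4% false calls. The TYMP fit recovered 96% and 100%, with 6.7% false calls. The simulated genes varied independently and all had the same dispersion, whereas the real genes rise and fall together. These rates therefore check the procedure and are not error rates of the real fits. The permutation test was checked on 200 simulated null pairs, of which 6.5% fell below 0.05, and on pairs with a true r of 0.6, of which 97.0% did.

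The named genes follow a rule set before the data were examined. It takes all members of the trifluridine and irinotecan lists and VEGFA. In each other category it takes the 2 members of highest level, the lowest, and the 2 of highest SD. It takes the 25 most variable genes, and in each fit the 12 positive and 8 negative genes of smallest p with a median of at least 5 CPM. A few genes that the rule takes are left out of the text. Genes whose level mostly reflects an inherited variant are never named. Where SDs tied at 2 decimals, all tied members are named, which was decided after their values were seen. Further members of a list given as examples are those of smallest p or steepest slope, chosen after their values were seen.

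Alternatives were size factors from DESeq2, the authors' TPM with a pseudocount of 1, a prior count of 0.5, no filter, leaving out the 4 libraries of lowest total, partial correlations and covariates for library and tissue measures, the 17 deeper and the 17 shallower libraries apart, DESeq2 and limma in place of edgeR, and other thresholds for variable genes. Leaving out the 3 libraries least similar to the others was added after seeing the data. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.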

Results

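RNA from archival colorectal cancer tissue was measured in 34 samples, each titled as a different patient, after capture of exons and untranslated regions. The study set out to relate treatment outcome to the expression of genes for DNA repair, trifluridine metabolism, cell cycle control and replication. Trifluridine is a thymidine analogue given together with tipiracil, an inhibitor of its breakdown. The design text counts 12 patients given it in combination and 21 given it alone, 33 in sum, whereas 34 samples are listed, and the labels assign no sample to a treatment or an outcome. All samples were therefore described as 1 group, and no comparison between treatments was made. Values below are medians with quartiles over n = 34 samples, since samples of both treatments may be mixed. CPM is not divided by transcript length, so the order of different genes within a list also depends on their length.

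The total expected count per sample was 19785445 in the median (quartiles 16801221 and 22443783) and ranged from 6936407 to 26096588. The second lowest total was 13866313. Genes with at least 1 count numbered 18317 in the median sample. Nuclear ribosomal RNA genes took 3.09% of counts in the median (quartiles 2.16% and 4.24%) and up to 11.3%. Of the 561 pairs of samples none agreed within sampling noise, the lowest chi-square per degree of freedom being 62.2. In 3 libraries the median correlation of log2 CPM with the other libraries was 0.631, 0.772 and 0.799, against 0.873 in the median library. No labelled batch was available, so relations were also computed within the 17 deeper and the 17 shallower libraries. This split by depth does not remove unlabelled differences of batch or treatment, which relations over all 34 samples may carry.

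Of the 19 trifluridine and nucleotide metabolism genes 18 passed the expression filter, and each of these reached 1 CPM in 34 of 34 samples. TK1, the thymidine kinase that phosphorylates trifluridine (GRCh38 chromosome 17, 78174075 to 78187233), had a median of 16.9 CPM (quartiles 11.9 and 22.3). TYMP, the phosphorylase that degrades trifluridine and is the target of tipiracil (chromosome 22, 50525752 to 50530056), had a median of 24.4 CPM (quartiles 15.0 and 41.8) and the widest spread of the list, with an SD of log2 CPM of 1.06 and a range of 6.38 to 219 CPM. TYMS, the thymidylate synthase inhibited by trifluridine monophosphate (chromosome 18, 657604 to 673578), stood at 20.9 CPM (quartiles 15.8 and 30.2). Its exons share 967 bases with ENOSF1 on the opposite strand, and because the use of strand in counting is not given in the sources used here, the TYMS level is uncertain.

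The nucleoside transporters SLC29A1 and SLC29A2 had medians of 44.1 CPM (quartiles 31.9 and 57.8) and 23.9 CPM (quartiles 13.4 and 26.3). SLC28A1 fell below the filter, reaching 1 CPM in 5 of 34 samples. Among the ribonucleotide reductase subunits, RRM2 had 68.6 CPM (quartiles 46.7 and 107), RRM2B 56.9 CPM (quartiles 43.5 and 77.6) and RRM1 39.8 CPM (quartiles 33.8 and 54.0). DPYD, the first enzyme of pyrimidine breakdown, had 30.1 CPM (quartiles 16.0 and 43.4), with an SD of log2 CPM of 0.94. The nucleoside diphosphate kinase NME2 was the most abundant member at 130.7 CPM (quartiles 92.1 and 157), and SAMHD1, a deoxynucleotide triphosphohydrolase, had 79.8 CPM (quartiles 59.6 and 105). Further medians were 39.9 CPM for TK2, 28.3 for NME1, 20.9 for DUT, 19.7 for DCTPP1, 11.6 for DTYMK and 7.69 for UPP1. NME1 and NME2 share exon sequence with a read-through gene, and DCTPP1 overlaps exons of an opposite-strand gene, so these levels are uncertain too.

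As a list, genes for irinotecan, a topoisomerase I poison, varied more between tumours than genes of similar level, though some members varied little. The median SD of log2 CPM over the 12 expressed members was 1.30, against 0.67 in random lists matched on expression, which was above 99.86% of 10000 such lists. TOP1, the drug's target (chromosome 20, 41028818 to 41124487), itself varied little, at 116 CPM (quartiles 94.3 and 146, SD 0.54). TDP1, which removes trapped topoisomerase I from DNA, had 16.1 CPM and an SD of 0.35, and TDP2 had 106 CPM and an SD of 0.81. CES2, the carboxylesterase that activates irinotecan, had 157 CPM (quartiles 87.6 and 234) and CES1 3.05 CPM (quartiles 2.15 and 10.7). The efflux transporters ABCG2, ABCB1 and ABCC2 had medians of 6.55, 36.4 and 6.51 CPM with SDs of 1.45, 1.5 and 1.80, whereas ABCC1 had 176 CPM and an SD of 0.53. CYP3A5 had 61.1 CPM (quartiles 40.1 and 102). CYP3A4 and SLCO1B1, both among the 12 expressed members, were near the floor, with medians of 0.299 and 0.467 CPM, so their own spread is imprecise. UGT1A1 was listed at 0 counts in 34 of 34 samples, as were the other 8 listed names of the UGT1A family, which shares exons. By counting error alone 0 counts allow up to 0.115 to 0.433 CPM, depending on the sample, and whether reads were assigned to these names at all is not given in the sources used here. VEGFA, whose product is the target of bevacizumab (chromosome 6, 43770184 to 43786487), was the most abundant gene of the VEGF axis at 415 CPM (quartiles 332 and 701).

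**Figure D1:**
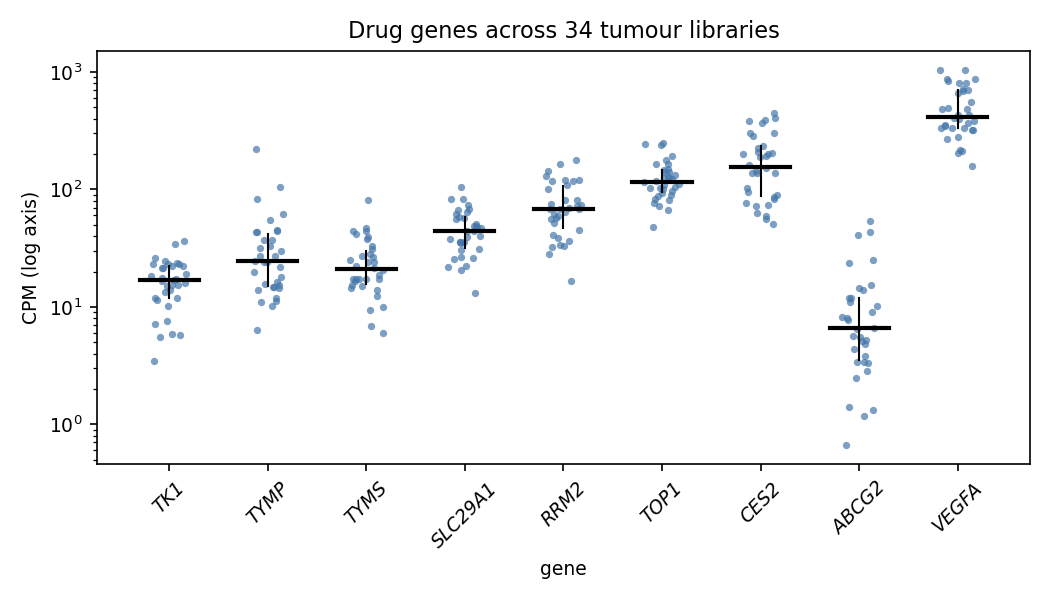
CPM on a log axis of 9 drug genes in the 34 libraries; each point is 1 library, the horizontal bar is the median and the vertical line joins the quartiles. TK1, TYMP and TYMS have medians of 16.9, 24.4 and 20.9 CPM, VEGFA of 415 CPM, and ABCG2 has the lowest median, 6.55 CPM.

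Of the repair categories 3 differed less between tumours than genes of similar level. The median SD of log2 CPM was 0.40 for mismatch repair, 0.45 for nucleotide excision repair and 0.43 for the DNA damage response, against 0.54, 0.55 and 0.54 in matched random lists (percentiles 1.6, 0.96 and 1.46 among 10000 lists). Nucleotide excision repair stayed below the 2.5 percentile in every alternative tried, but mismatch repair rose to percentile 4.86 and the DNA damage response to 15.7 with the authors' TPM, and to 3.72 and 4.46 without the 4 shallowest libraries. Mismatch repair was also at 5.58 without the 3 least similar libraries, and the DNA damage response at 3.01 with size factors and 2.93 when adjusted for the epithelial and fibroblast scores. Base excision repair (0.52), the proofreading polymerases (0.51), non-homologous end joining (0.47), homologous recombination (0.60, against 0.57 in matched lists), replication (0.68), cell cycle checkpoints (0.73) and the trifluridine list (0.69) lay between percentiles 8.51 and 96.86. The checkpoint genes passed into the top 2.5% in 5 of the alternatives, at percentiles 97.51 to 99.62, and base excision repair fell below the 2.5 percentile without the 4 shallowest libraries. By contrast the marker lists of normal colon absorptive cells, goblet cells and hepatocytes had median SDs of 2.87, 2.90 and 3.32. Without the 3 least similar libraries these were 2.70, 2.79 and 2.07, the last over 3 expressed members. The percentiles describe lists of genes, which are not independent replicates.

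**Figure D2:**
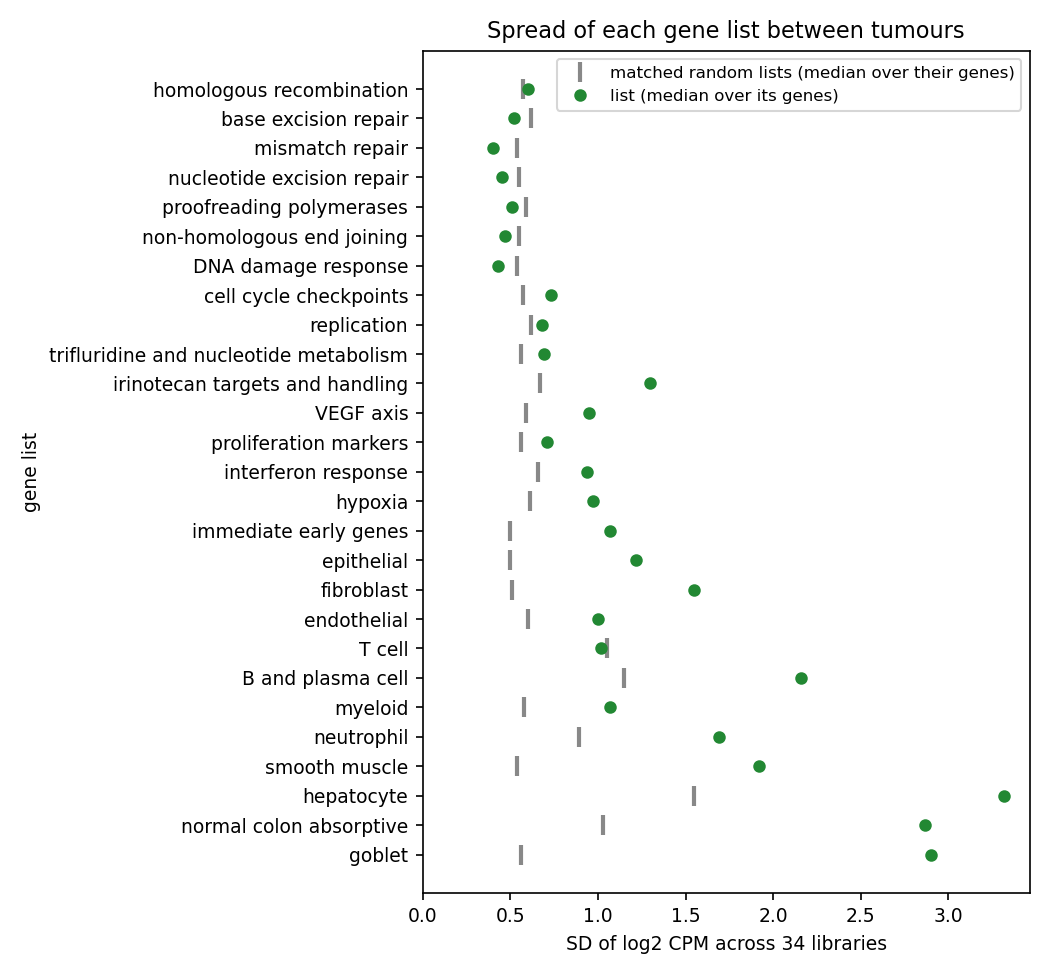
Median over each list's genes of the SD of log2 CPM across 34 libraries (circles) and the median over matched random lists (grey bars), for 27 lists. Mismatch repair, at 0.40, is the lowest, and the hepatocyte markers, at 3.32 (2.07 without the 3 least similar libraries), are the highest.

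In homologous recombination, RAD50 and MRE11, partners in the complex that senses double-strand breaks, were the most abundant members at 142.4 CPM (quartiles 128 and 176) and 111 CPM (quartiles 94.1 and 128). In the GENCODE annotation 79.7% of the exon bases of RAD50 are shared with another gene name on the same strand. Whether that name is among those counted was not checked, so it is uncertain whether the RAD50 level is affected. RAD51C was the lowest at 7.44 CPM, XRCC2 varied most with an SD of 0.82, and BRCA2 and RAD54L followed with 0.75 each. In base excision repair PARP1 had 80.2 CPM and APEX1, the abasic site endonuclease, 49.5 CPM. The glycosylase NEIL1 was the most variable there (9.30 CPM, SD 1.10), followed by NTHL1, the lowest member (4.53 CPM), and NEIL3 (8.31 CPM), with SDs of 0.71 each. NEIL1 shares 26.4% of its exon bases with MAN2C1 on the opposite strand. In mismatch repair MLH3 stood at 99.3 CPM and MSH6 at 50.6 CPM, and the exonuclease EXO1 was both the lowest and the most variable at 14.6 CPM with an SD of 0.72. RAD23B (254 CPM) and DDB1 (124 CPM) led nucleotide excision repair, ERCC8 was the lowest at 10.3 CPM, and DDB2 and XAB2 varied most, with SDs of 0.61 and 0.58.

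POLE, the catalytic subunit of the leading-strand polymerase, had 107 CPM (quartiles 91.0 and 119) and POLD3 51.1 CPM. The catalytic subunit POLD1 was the most variable member of the proofreading polymerase list, with 32.7 CPM and an SD of 0.73, ahead of POLE2 with 3.61 CPM and 0.63. PRKDC, the kinase of non-homologous end joining, had 548 CPM (quartiles 454 and 887, SD 0.65), XRCC5 178 CPM, XRCC6 an SD of 0.61, and PAXX, the lowest member, 7.25 CPM. In the DNA damage response ATM had 257 CPM and MDM2 211 CPM, CHEK2 was lowest at 6.68 CPM, and CLSPN varied most, with an SD of 0.69. CCND1 (377 CPM) and CDK6 (309 CPM) led the checkpoint genes. CDKN2A, which encodes an inhibitor of CDK4 and CDK6, was the lowest and most variable checkpoint gene, with 4.45 CPM (quartiles 2.64 and 8.47, SD 1.58), and PKMYT1 and MAD2L1 followed with SDs of 0.96 each. In replication POLA1 had 95.3 CPM and MCM7 82.2 CPM, RPA3 was the lowest at 1.93 CPM with an SD of 1.21, and PCNA had an SD of 0.98.

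Members of 6 of the 10 categories rose and fell together more than matched lists, and replication had the highest mean pairwise r. The mean pairwise r within the replication list was 0.46, within cell cycle checkpoints 0.32 and within homologous recombination 0.26, each above all 10000 matched random lists, whose medians were 0.00. It was 0.13 for the trifluridine list (percentile 99.87), 0.11 for base excision repair (99.86) and 0.10 for the DNA damage response (97.96). With the authors' TPM the trifluridine and base excision repair lists fell to percentiles 84.35 and 94.93, and without the expression filter the DNA damage response fell to 95.09. Mismatch repair, at 0.15, reached percentile 97.26, just short of the top 2.5%, which it entered without the 3 least similar libraries (98.67) and when adjusted for the epithelial and fibroblast scores (98.43), and proofreading polymerases, nucleotide excision repair and non-homologous end joining reached 96.14, 91.96 and 73.17. The proliferation markers had a mean pairwise r of 0.73, the VEGF axis 0.56 and the fibroblast markers 0.90. Adjusted for the epithelial and fibroblast scores, that of the VEGF axis was 0.17.

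The scores of the 10 categories were positively correlated with one another. Of the 45 pairs, 43 passed a two-sided permutation test of Pearson's r (100000 resamples, Benjamini-Hochberg adjusted over the 45 pairs at 0.05) and 42 passed by Spearman's rho. The median r was 0.64. Cell cycle checkpoints and replication had the highest r, 0.92 (rho 0.92, p = 1e-05, the smallest the resamples can give, adjusted p = 3.7e-05), and r was 0.91 without the 2 samples farthest from the median. Base excision repair and proofreading polymerases followed with r = 0.83 (rho 0.82, p = 1e-05, adjusted p = 3.7e-05, 0.78 without the 2 samples), then proofreading polymerases and replication with r = 0.81 (rho 0.84, p = 1e-05, adjusted p = 3.7e-05, 0.82 without the 2 samples). Homologous recombination and nucleotide excision repair did not pass (r = 0.17, rho 0.24, p = 0.33, adjusted p = 0.33), nor did the DNA damage response and the trifluridine list (r = 0.31, rho 0.31, p = 0.074, adjusted p = 0.076). Homologous recombination and the trifluridine list passed by r alone (r = 0.35, p = 0.041, adjusted p = 0.043, rho 0.27, adjusted p = 0.13). Without the 2 samples r was similar, 0.29, and p was 0.099. This r lay at percentile 75.8 of random lists matched on size and level.

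Random lists of matched size and level were themselves correlated, with a median r of 0.13, and 27 of the 45 category pairs lay in the top 2.5% of such random pairs. Given the proliferation marker score, 24 pairs passed. Library measures moved with some scores and with the main axes of variation as well. Principal component 2 of log2 CPM (14.2% of variance) followed the log10 library total (r = 0.73, rho 0.63, adjusted p = 0.0025). Component 1 (19.5%) followed the number of detected genes (r = 0.60, rho 0.60, adjusted p = 0.0089). The fibroblast score rose with the share of the 100 most abundant genes (r = 0.45, rho 0.46, adjusted p = 0.04). By rho alone it rose with the library total (rho 0.46, adjusted p = 0.044). The log10 library total correlated with the nucleotide excision repair score (r = 0.65, rho 0.49, adjusted p = 0.0025 over 76 relations) and with the trifluridine score (r = 0.53, rho 0.54, adjusted p = 0.0089), and with non-homologous end joining by r alone (r = 0.48, rho 0.25, adjusted p = 0.04 and 0.32). The share of ribosomal RNA rose with the trifluridine (r = 0.51, rho 0.65, adjusted p = 0.015), base excision repair (r = 0.45, rho 0.45, adjusted p = 0.04) and nucleotide excision repair scores (r = 0.46, rho 0.47, adjusted p = 0.041). The number of detected genes fell with the nucleotide excision repair score (r = -0.60, rho -0.37, adjusted p = 0.0025 and 0.1), and by rho alone with that of mismatch repair (r = -0.40, rho -0.45, adjusted p = 0.089 and 0.044). The share of the 100 most abundant genes rose with the trifluridine (r = 0.49, rho 0.49, adjusted p = 0.018) and nucleotide excision repair scores (r = 0.46, rho 0.35, adjusted p = 0.04 and 0.14), and by rho alone it fell with the homologous recombination score (r = -0.37, rho -0.44, adjusted p = 0.13 and 0.049). Within the 17 deeper libraries 40 pairs passed and within the 17 shallower ones 36.

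**Figure D3:**
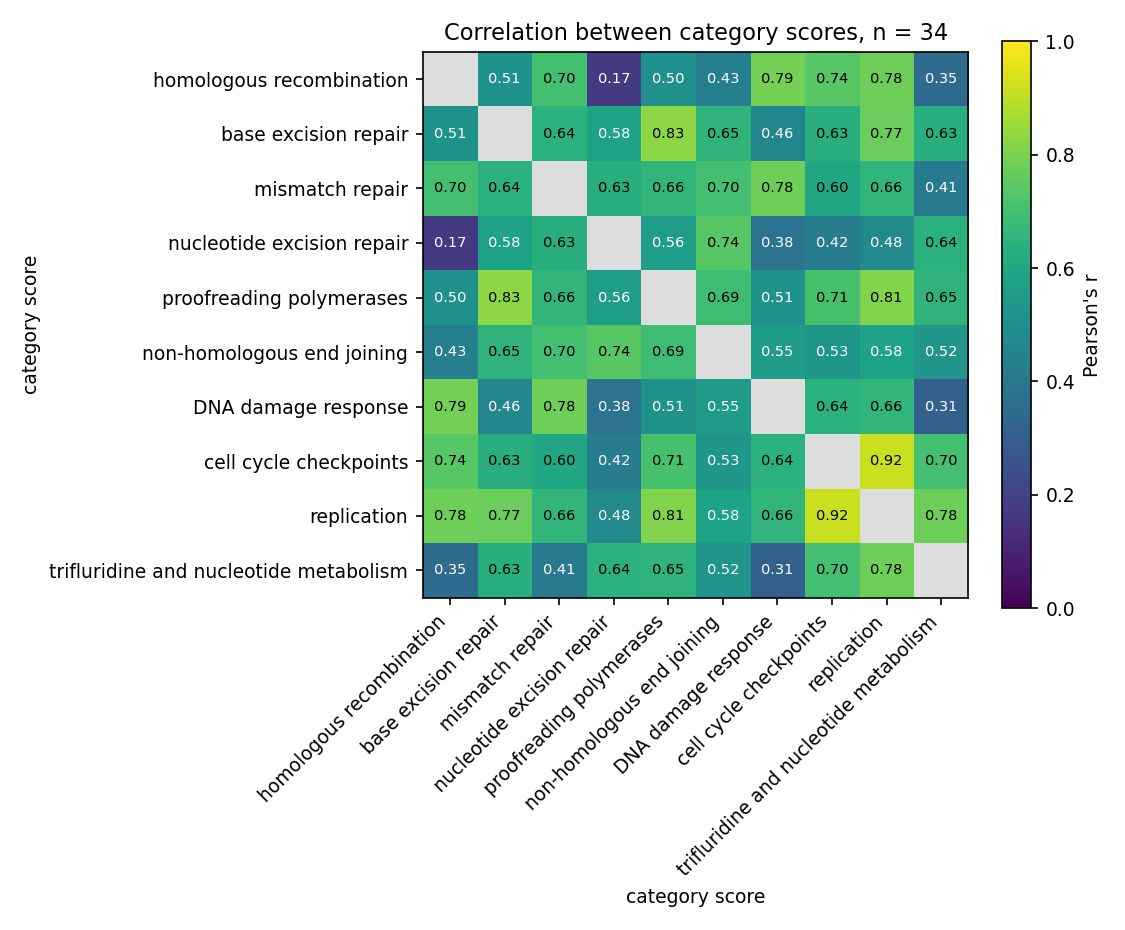
Pearson's r between the scores of the 10 categories over 34 libraries, where a score is the mean z-scored log2 CPM of a list's genes without genes shared by the pair; grey squares are not defined. The highest r is 0.92, between cell cycle checkpoints and replication, and the lowest is 0.17, between homologous recombination and nucleotide excision repair.

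Drug genes followed different tissue scores. TK1, TYMS and RRM2 rose with the proliferation markers, TYMP with endothelial, fibroblast, myeloid and interferon genes, and VEGFA with hypoxia genes. Of 72 pairs of 9 genes and 8 scores, 15 passed the permutation test of Pearson's r after adjustment, 12 of them positive. For TK1 and proliferation r was 0.76 (rho 0.71, p = 1e-05, adjusted p = 0.00014, 0.69 without the 2 samples farthest from the median). It was 0.76 within the deeper and 0.77 within the shallower libraries. RRM2 had r = 0.79 with proliferation (rho 0.74, p = 1e-05, adjusted p = 0.00014, 0.71 without the 2 samples, 0.91 and 0.61 in the deeper and shallower libraries, the latter with adjusted p = 0.077). TYMS had r = 0.59 (rho 0.62, p = 0.0002, adjusted p = 0.0016, 0.64 without the 2 samples), but 0.77 within the deeper and 0.32 within the shallower libraries, where it did not pass.

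TYMP had r = 0.83 with the endothelial score (rho 0.74, p = 1e-05, adjusted p = 0.00014, 0.72 without the 2 samples), and 0.92 and 0.67 within the deeper and shallower libraries. It had r = 0.71 with the interferon score (rho 0.76, p = 1e-05, adjusted p = 0.00014, 0.77 without the 2 samples, 0.65 and 0.79 within the deeper and shallower libraries) and r = 0.70 with the fibroblast score (rho 0.66, p = 1e-05, adjusted p = 0.00014, 0.70 without the 2 samples, 0.58 and 0.78). With the myeloid score r was 0.65 (rho 0.53, p = 8e-05, adjusted p = 0.00072, 0.62 without the 2 samples, 0.57 and 0.68). Within the deeper libraries the fibroblast and myeloid relations did not pass (adjusted p = 0.084 for both). Given the epithelial and fibroblast scores, the endothelial and myeloid relations no longer passed (r = 0.40 and 0.31), while the interferon relation did (r = 0.68, adjusted p = 0.00036). The negative relation with the epithelial score (r = -0.65, rho -0.49, p = 6e-05, adjusted p = 0.00072) was weaker without the 2 samples farthest from the median of TYMP (r = -0.34, p = 0.061), so over all 34 samples it rests partly on those 2. It was -0.25 within the shallower and -0.83 within the deeper libraries (adjusted p = 0.77 and 0.0012), and -0.57 without the 3 least similar libraries (adjusted p = 0.0065). TYMP also rose with the share of counts taken by the 100 most abundant genes (r = 0.50, rho 0.50, adjusted p = 0.023 over 76 relations).

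VEGFA had r = 0.66 with the hypoxia score (rho 0.58, p = 7e-05, adjusted p = 0.00072, 0.59 without the 2 samples, 0.58 and 0.78 within the deeper and shallower libraries, the former with adjusted p = 0.084). The other 6 relations passed less firmly. TOP1 had r = 0.48 with proliferation (rho 0.57, p = 0.0041, adjusted p = 0.024, 0.56 without the 2 samples) and -0.49 with the T cell score (rho -0.50, p = 0.0034, adjusted p = 0.024, -0.48). SLC29A1 had r = 0.48 with the fibroblast score (rho 0.53, p = 0.0041, adjusted p = 0.024, 0.58 without the 2 samples) and 0.46 with the myeloid score (rho 0.57, p = 0.0053, adjusted p = 0.029, 0.56). CES2 passed with the myeloid score by r alone (r = -0.44, p = 0.0084, adjusted p = 0.04, rho -0.39, adjusted p = 0.12, r = -0.42 without the 2 samples). RRM2 passed with the epithelial score by r alone (r = 0.45, p = 0.0079, adjusted p = 0.04, rho 0.35, adjusted p = 0.17), which rested on 2 samples (0.27 without them, p = 0.14). With size factors neither CES2 nor RRM2 passed in these relations by r (adjusted p = 0.056 and 0.057). By Pearson's r none of these 6 passed within the deeper libraries, within the shallower ones or without the 3 least similar libraries. Within the deeper libraries r was 0.51 to 0.64, or -0.51 and -0.58 for the negative relations. By rho all but that of RRM2 passed there (adjusted p = 0.016 to 0.04). Within the shallower ones r ran from -0.48 to 0.38 and none passed by rho. Without the 3 least similar libraries only TOP1 (adjusted p = 0.011 and 0.033) and SLC29A1 with the myeloid score (0.011) passed by rho.

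**Figure D4:**
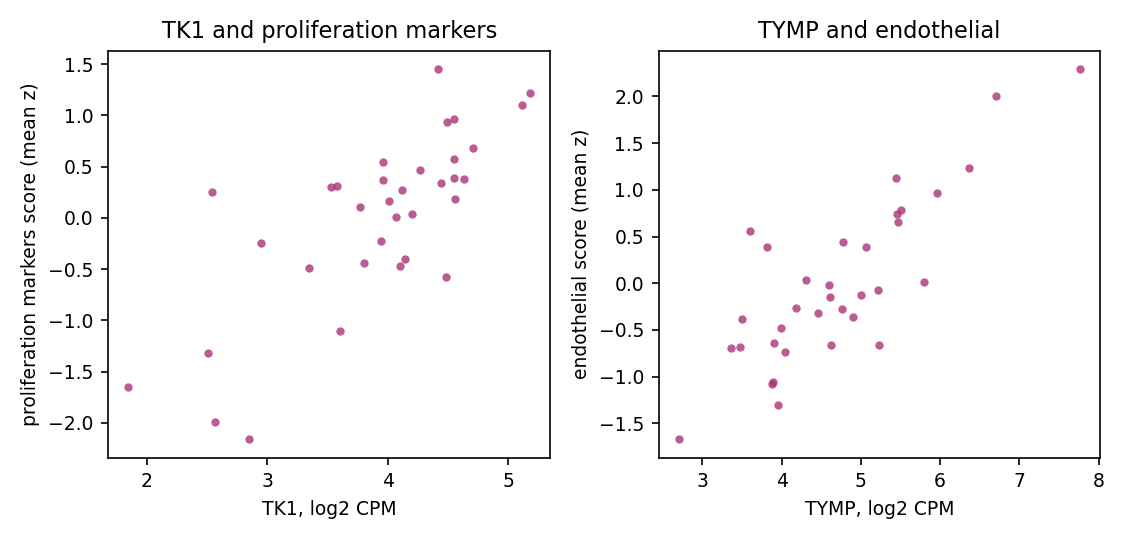
Log2 CPM of TK1 against the proliferation score (left) and of TYMP against the endothelial score (right), where each point is 1 of 34 libraries and a score is a mean z value. Both rise together, with r = 0.76 and r = 0.83.

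TK1 and TYMP, the activating and the degrading enzyme of trifluridine, were not correlated beyond chance. Pearson's r was -0.01 (rho -0.04, p = 0.95 and p = 0.82, permutation test, 100000 resamples, 1 relation) and -0.05 without the 2 samples farthest from the median of TK1. The log2 difference TK1 minus TYMP had a median of -0.73 (quartiles -1.63 and 0.14) and was above 0 in 11 of 34 samples.

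Replication, proliferation and checkpoint genes were among those that rose with TK1, with 22, 16 and 10 members of these lists passing. Among 15635 genes tested by edgeR's quasi-likelihood test with log2 CPM of TK1 as covariate, 1186 passed a Benjamini-Hochberg adjusted p of 0.05, 702 with a positive and 484 with a negative slope. With size factors in place of TMM the split was 565 and 614, and with limma on the authors' TPM it was 711 and 222, so the balance of directions depends on the scaling. With the proliferation score as a covariate 666 genes passed with a positive and 775 with a negative slope, of which 135 and 143 were shared with the 702 and 484. A slope of 1 means a doubling per doubling of TK1. The 12 positive genes of smallest p were the mitotic genes KIF22 (slope 0.62, SE 0.07, adjusted p = 3.5e-06), AURKB (0.83, SE 0.10), TACC3 (0.68), BUB1B (0.68) and KIFC1 (0.77). They also held the replication factor TICRR (1.06, SE 0.13), the repair gene FANCA (0.73), the transcription factor MYBL2 (1.02), and the histone genes H2AX (0.62), HIST1H2AL (1.02), HIST1H2AG (0.96) and HIST1H2AH (0.97). The histone copies share near-identical sequence, so their separate levels are uncertain. The 8 negative genes were LGALS8 (-0.47, SE 0.07, adjusted p = 2.6e-05), TRIM23 (-0.45), the EGFR ligand gene TGFA (-0.68, SE 0.10), ERBB2IP (-0.49), the lysosomal sulfatase gene IDS (-0.47), ZBTB20 (-0.57), SLC37A2 (-1.77, SE 0.30) and CREBRF (-0.38). SLC37A2 did not pass with limma on the authors' TPM (slope -0.86, adjusted p = 0.074) or with the proliferation score as a covariate (-0.51, adjusted p = 0.51), and in the latter fit MYBL2 (0.49) and IDS (-0.35) did not pass either.

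By list, 22 of the 33 replication genes rose with TK1 and none fell, or 27 adjusted over the list alone. CDT1 (slope 0.92, SE 0.13), CDC45 (0.88, SE 0.14) and MCM2 (0.77, SE 0.12) had the smallest p. The list passed limma's camera test (adjusted p = 9.1e-27, and adjusted p = 0.0034 with an estimated correlation). Of the proliferation markers 16 of 20 rose, or 20 adjusted over the list alone (camera adjusted p = 2.3e-25, and adjusted p = 0.0095 with an estimated correlation). Of the checkpoint genes 10 of 23 rose, or 12 adjusted over the list alone together with 2 that fell (adjusted p = 5.7e-10, and adjusted p = 0.045 with an estimated correlation). Among proofreading polymerases 5 of 8 rose, led by POLD1 (slope 0.70, SE 0.11), also 5 adjusted over the list alone (adjusted p = 0.00099, and adjusted p = 0.0078 with an estimated correlation). Of base excision repair 3 of 19 rose (APEX1, APEX2 and XRCC1, picked out after their values were seen), or 6 adjusted over the list alone (adjusted p = 0.00032, and adjusted p = 0.0095 with an estimated correlation).

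For 4 further lists the camera call was lost with an estimated correlation. Of homologous recombination 7 of 19 rose, or 9 adjusted over the list alone, with BLM (slope 0.69, SE 0.11) of smallest p (adjusted p = 1.8e-06, and adjusted p = 0.069 with an estimated correlation). Of the trifluridine list 6 of 17 rose, among them TYMS (slope 0.75, SE 0.14), DTYMK (0.57, SE 0.11) and RRM2 (0.56, SE 0.13), and RRM2B fell (-0.43, SE 0.11), with 8 and 1 adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.17 with an estimated correlation). Of the DNA damage response 4 of 17 rose, or 6 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation), and of mismatch repair 2 of 8, or 4 (adjusted p = 0.028, and adjusted p = 0.17 with an estimated correlation). No member of the epithelial, fibroblast, endothelial, T cell or myeloid lists passed in the TK1 fit.

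Genes that followed TYMP were more numerous and included most of the endothelial, fibroblast and myeloid markers. Of 15635 genes 3640 passed, 1997 with a positive and 1643 with a negative slope. Without the expression filter the split was 2187 and 4068, and with DESeq2 2143 and 2279. Without the 3 least similar libraries 2210 genes passed, and with the epithelial and fibroblast scores as covariates 160. The positive genes of smallest p were SPI1, a myeloid transcription factor (slope 0.89, SE 0.07, adjusted p = 1.9e-10), the endothelial genes EGFL7 (0.81, SE 0.07), ENG (0.86, SE 0.07) and PLXND1 (0.78), the chemokine gene CCL2 (0.99, SE 0.10), and SH2B3 (0.48), GNAI2 (0.63), SIPA1 (0.57), HOMER3 (0.77), PREX1 (0.61), DYSF (0.80) and PLEKHO2 (0.68). Among the negative genes of smallest p were ZSWIM5 (-0.62, SE 0.07, adjusted p = 1.9e-07), TMEM182 (-0.50), FNBP1L (-0.45), VSIG10 (-0.51), NAPEPLD (-0.58), UGT8 (-0.87, SE 0.14) and the histone demethylase gene KDM7A (-0.48). With the epithelial and fibroblast scores as covariates 12 of the 20 genes chosen by this order no longer passed. TYMP shares 347 exon bases with ODF3B on the same strand, so reads there are uncertain.

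All 10 fibroblast markers rose with TYMP, led by POSTN (slope 1.29, SE 0.22) and COL1A1 (1.17, SE 0.19), and 9 of 10 endothelial markers, 11 of 12 myeloid markers and 10 of 11 VEGF axis genes rose. Adjusted over the list alone the counts were 10, 10, 11 and 10. Camera gave adjusted p = 1.7e-09, 1.9e-12, 2.9e-07 and 7e-08 for the 4 lists, and adjusted p = 0.18, 0.076, 0.19 and 0.13 with an estimated correlation. Within the VEGF axis PGF (slope 0.75, SE 0.11), FLT4 (0.69, SE 0.11) and the neuropilin genes NRP1 (0.68, SE 0.09) and NRP2 (0.68, SE 0.14) had the steepest slopes, while VEGFA itself did not pass (slope 0.07, SE 0.11, adjusted p = 0.69). The other members that did not pass were CLDN5 among the endothelial and LYZ among the myeloid markers, picked out after their values were seen. Of the interferon genes 9 of 16 rose, or 12 adjusted over the list alone, with GBP1 (slope 0.52, SE 0.07) of smallest p (adjusted p = 1.5e-05, and adjusted p = 0.14 with an estimated correlation). Of the immediate early genes 8 of 10 rose, also 8 adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.48 with an estimated correlation). Of the epithelial markers 7 of 13 fell, or 11 adjusted over the list alone, TSPAN8 by the smallest p (slope -0.81, SE 0.22, camera adjusted p = 2.8e-07, and adjusted p = 0.18 with an estimated correlation). Of the goblet markers 4 of 6 fell, or 5 adjusted over the list alone (adjusted p = 0.003, and adjusted p = 0.34 with an estimated correlation). Smaller calls were made for neutrophil markers, 3 of 5 of which rose, or 5 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation), and T cell markers, 1 of 9 of which rose, also 1 adjusted over the list alone (0.046, and adjusted p = 0.6 with an estimated correlation). Camera also placed the normal colon absorptive (adjusted p = 0.0027), proliferation (0.0024), checkpoint (0.022), homologous recombination (0.032) and replication lists (0.047) lower with TYMP, with 0, 1, 4, 0 and 1 members falling, or 0, 0, 4, 0 and 0 adjusted over the list alone. With an estimated correlation these had adjusted p = 0.53, 0.61, 0.6, 0.57 and 0.79. Without the 3 least similar libraries none of these 5 passed (adjusted p = 0.11, 0.1, 0.18, 0.1 and 0.18), and without the 4 shallowest libraries homologous recombination and replication did not (adjusted p = 0.06 for both). No list's call in the TYMP fit held with an estimated correlation, and 15 passed with the preset one.

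One isoform led in every library for 5 of the 14 genes examined. TYMS, TOP1 and POLE have a single listed isoform, and for TK1 NM_003258.4 took all of the gene's expected counts in the median library. For SLC29A1 NM_004955.2 led in 34 of 34 libraries with a median of 65.2% (quartiles 57.7% and 70.3%). For CES2 NM_003869.5 led in 33 with 85.1%, and for RRM2 NM_001034.3 led in 29 with 90.2%. TYMP was split between NM_001953.4, which led in 17 of 34 libraries with a median of 46.6% (quartiles 33.2% and 52.0%), and NM_001113756.2, with a median of 44.1%. The leading isoform of POLD1 took 78.7%, of SAMHD1 58.2%, of DUT 54.0% and of VEGFA 29.4%. For ABCG2 XM_005263356.1 led in 12 libraries, the most for any of its isoforms, with a median of 19.4%, while NM_004827.2 had a median of 21.0%. ABCG2 had few counts, so its split between isoforms is imprecise. These shares are estimates in which reads common to isoforms were divided by the authors' quantification.

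Goblet cell and normal colon absorptive markers were among the most variable genes. Among 12401 genes with a median of at least 5 CPM, the goblet cell chloride channel regulator CLCA1 ranked first, with a median of 53.1 CPM (quartiles 3.19 and 236) and an SD of log2 CPM of 4.02. The goblet and secretory genes MUC2 (2685 CPM, quartiles 524 and 4391, SD 3.16), REG4 (50.8 CPM, SD 2.86), SPINK4 (10.0 CPM, SD 2.93), ITLN1 (13.0 CPM, SD 3.23) and REG1A (5.43 CPM, SD 3.73) were among the first 25. So were CLCA4 (10.5 CPM, SD 3.47), SLC26A3 (65.7 CPM, SD 3.18), CA1 (5.48 CPM, SD 3.00) and the secreted lectin gene ZG16 (6.95 CPM, SD 3.10), all held in the normal colon absorptive list. The mucin genes MUC5AC and MUC17 had SDs of 2.89 and 2.86, the epithelial immunoglobulin receptor gene PIGR 3.09, the plasma cell gene JCHAIN 2.97, the matrix protease gene MMP3 3.26, NXPE4 3.19, L1TD1 3.04 and the ribosomal RNA gene RNA5-8S5 2.90. The other 7 were the read-through genes RPL17-C18orf32, HNRNPUL2-BSCL2, C8orf44-SGK3, MINOS1-NBL1 and SPECC1L-ADORA2A and the histone copies HIST2H2AA4 and HIST2H3A, whose SDs ran from 2.91 to 3.53 and whose reads could be divided among genes of shared sequence.

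Among the 500 most variable genes were 7 of 7 normal colon absorptive markers (Fisher's exact test, adjusted p = 2e-09), 7 of 10 fibroblast markers (adjusted p = 1.1e-07), 5 of 6 goblet markers (adjusted p = 2.4e-06), 4 of 6 smooth muscle markers (adjusted p = 0.00011), 2 of 3 neutrophil markers (adjusted p = 0.011) and 3 of 13 epithelial markers (adjusted p = 0.028). None of the 9 endothelial and 12 myeloid markers was among them. Fisher's test treats genes as independent, but markers of a list rose and fell together. Its p-values are therefore a description and do not measure the spread between samples. With a minimum of 1 CPM in place of 5, 16 of the first 25 genes were shared, and the enrichments of fibroblast (adjusted p = 0.11), neutrophil (0.34) and epithelial markers (1) were lost. That of epithelial markers was also lost without the 3 least similar libraries.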

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

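Most of the comparisons counted here kept their direction and their side of the threshold. Among the 495 comparisons of category pairs with an alternative, 446 kept both. So did 90 of 131 for drug gene relations and 468 of 510 for list percentiles. These totals include the prior count of 0.5, which could change little. With it 43 category pairs and 15 drug gene relations passed, the same numbers as in the main setting. For the named genes the numbers were 176 of 180 in the TK1 fit and 168 of 180 in the TYMP fit. These genes were chosen by smallest p in the main fits, so they were likely to keep their call. Of the 3640 genes called in the TYMP fit, 76 positive and 31 negative ones also passed with the epithelial and fibroblast scores as covariates. With DESeq2 it was 1954 and 1643. The alternative without the 3 least similar libraries was chosen after seeing the data. The shallowest library had 6936407 counts, which limits the precision of genes near 1 CPM.

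With TPM, 5 lists in place of 3 lay in the top 2.5% of level, 1 list in place of 3 lay below the 2.5 percentile of spread, and 16 of the 25 most variable genes were shared. Without the filter 7 lists lay in the top 2.5% of level, as more weakly expressed genes enter the background, and 6255 genes passed in the TYMP fit. With a minimum median of 1 CPM, 16 of the first 25 and 219 of the first 500 variable genes were shared, since more genes were ranked. DESeq2 called 1782 genes in the TK1 fit. With camera's estimated correlation 5 lists in place of 9 passed in the TK1 fit and 0 in place of 15 in the TYMP fit. In each list that lost its call the estimated correlation lay above the preset 0.01.

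With the proliferation score as a covariate the TK1 fit shared 135 positive and 143 negative genes with the 1186, and the median slope size of those 1186 fell from 0.43 (median SE 0.11) to 0.35 (median SE 0.16). Given the proliferation score 24 category pairs passed, and 5 pairs changed sign: homologous recombination with base excision repair (-0.01), nucleotide excision repair (-0.13), proofreading polymerases (-0.11) and the trifluridine list (-0.33), and the DNA damage response with the trifluridine list (-0.09). Drug gene relations that passed numbered 9 without the 3 least similar libraries, 5 of 54 given the epithelial and fibroblast scores, 7 within the deeper and 6 within the shallower libraries, against 15. The deeper and the shallower libraries hold 17 samples each. The hepatocyte list could not be tested without the 4 shallowest libraries. The r of TK1 and TYMP, -0.01, was 0.11 given the epithelial and fibroblast scores and 0.02 within the shallower libraries, never past the threshold. In the TYMP fit 2210 genes passed without the 3 least similar libraries, 160 with the epithelial and fibroblast scores and 924 with the myeloid and T cell scores as covariates. The median slope size of the 3640 genes was 0.42 (median SE 0.10) in the main fit. It was 0.20 (median SE 0.16) with the epithelial and fibroblast scores and 0.34 (median SE 0.14) with the myeloid and T cell scores. Adjusting for the epithelial and fibroblast scores put the co-variation of those 2 lists at percentile 0.0, which the adjustment itself brings about. Where no cause is given, the cause was not tested.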

Other observations

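Markers of tissues other than tumour epithelium were unevenly spread over the samples. The summed level of the hepatocyte markers had a median of 6.53 CPM (quartiles 3.25 and 18.4) and exceeded 10 times that median in 4 of 34 libraries. The smooth muscle sum had a median of 441 CPM (quartiles 320 and 857) and exceeded 10 times its median in 4 libraries. The sum of B and plasma cell markers had quartiles of 105 and 903 CPM, and that of normal colon absorptive markers of 66.1 and 733 CPM. The lung alveolar and adipocyte sums were low, with medians of 1.72 and 4.60 CPM, and exceeded 10 times the median in 1 and 2 libraries. So did the sums of neutrophil markers in 2 libraries and of fibroblast and normal colon absorptive markers in 1 each. T cell markers summed to 125 CPM (quartiles 90.6 and 149), and their spread, a median SD of 1.02, was at percentile 44.1 of matched lists. The immediate early genes, which respond to handling of tissue as well as to growth signals, had a mean pairwise r of 0.70 and a median SD of 1.07. The median SD was 0.94 for interferon, 0.97 for hypoxia, 1.00 for endothelial, 1.07 for myeloid, 1.22 for epithelial, 1.55 for fibroblast, 1.69 for neutrophil, 1.92 for smooth muscle and 2.16 for B and plasma cell genes. Without the 3 least similar libraries the median SD of the epithelial markers was 0.66 and their mean pairwise r 0.31, against 0.62 with all libraries.

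The tests of this part that were chosen only after the result was seen are those of permuted covariates and of tissue composition for TYMP. Leaving out the 3 least similar libraries was added after seeing the data, and the shuffle test after seeing the SDs of the sums, each with its bounds set before its own result. The labels give no group to set against these patterns, so no biological explanation from the design was tested. The category scores rose and fell together, with 43 of 45 pairs past the threshold. Library depth, and tissue composition as far as the epithelial and fibroblast scores measure it, are argued against as the whole cause. Given library total and detected genes 44 pairs passed, and 44 given those scores. Other cell types were not adjusted for. Passing is judged against no correlation, while matched random lists had a median r of 0.13. These counts therefore do not address what the categories share with random lists. Given the proliferation marker score 24 pairs passed and the median r fell from 0.64 to 0.38, which lies between the bounds set beforehand. A shared proliferation level may therefore account for part of the co-variation, and what holds the rest together stays open.

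The number of genes following TYMP, 3640, was not reached by chance orders of its values. Only 1 of 41 orders, the real one, gave as many, and the highest other gave 847. For TK1, with 1186 genes, it was likewise 1 of 41, with 505 the highest other. With the epithelial and fibroblast scores as covariates the median slope size of the TYMP genes fell from 0.42 to 0.20, while the median SE rose from 0.10 to 0.16, so calls ended through both, which is consistent with TYMP following the share of stroma in the tissue. The 3 least similar libraries are argued against as the whole cause, since the median slope size without them was 0.39.

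Of the 25 most variable genes, 7 were read-through genes or histone copies listed at 0 counts in 6 to 9 of 34 libraries. Summed with their partner names, all 7 had an SD under 1.5, from 0.24 to 0.97 against 2.93 to 3.55 alone (log2 CPM with a pseudocount of 0.1 CPM), but for 5 of them shuffled values gave sums under that bound as well, so this could not decide. In a shuffle test, the SD of the sum was below 95% of the sums with shuffled values for 4 of the 7 genes (RPL17-C18orf32, C8orf44-SGK3, HIST2H2AA4 and HIST2H3A). For HIST2H2AA4 the SD was 0.83 against a shuffled median of 1.76. Reads exchanged between names of shared sequence may contribute to the spread of these 4, but 4 lies between the bounds set beforehand, so this stays open for the 7 as a set.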
